A study of Mus musculus with 8 samples.

How the data were processed

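Lung CD45-positive cells of mice with flank Lewis lung carcinoma were measured in 4 groups (AREG-sufficient or AREG-KO tumors, irradiated with 20 Gy or not), each as 1 gene expression library and 1 hashtag library of the same cells. Per the labels, lungs were digested with collagenase at 1 mg/mL and DNase at 200 ug/mL for 45 min at 37 C and passed through a 70 um strainer. The authors deposited counts, 1 matrix of UMI counts per library pair with genes and 4 hashtags together, made per the submitters' processing notes with Cell Ranger 7.1.0 on mm10. The barcodes are the cells called there, and each holds at least 500 gene UMIs. The annotation release is not stated. Gene coordinates are those of a GENCODE annotation of GRCm38.

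Hashtags were assigned per library with a 2-component Gaussian mixture on the log10 count of each hashtag, and barcodes positive for none or for more than 1 hashtag were left out (3.42, 8.82, 7.51 and 9.22% were positive for several, in the order unirradiated and irradiated AREG-sufficient, unirradiated and irradiated AREG-KO). Cells with at least 500 UMIs, at least 200 genes and under 10% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5 scored doublets, with a score threshold of 0.2 set after the score distributions were seen, and 3.6, 3.62, 4.53 and 5.6% of hashtagged barcodes were over it. Clusters came from 2000 variable genes, 30 principal components, 15 neighbors and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 over all libraries together, with no integration. Clusters were named from marker lists fixed before the data were examined, with at least 3 markers detected at a log2 fold of 1, and a name ends in -like because it rests on transcripts alone. Clusters were left unnamed when over 30% of their cells were called doublets, when their leading genes were those of another list, or, by a rule added after seeing the data, when a T-cell-like cluster held over 100 CPM of Rag1 and Dntt. The other tools were Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

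The replicate is the hashtag pool, with 4 per library and 16 in all, a condition fixed before the data were examined. UMI counts were summed per pool and class, for pools with at least 20 cells of the class. Neutrophil-like cells gave 12301 cells in all (236 to 1397 per pool, 1275389 to 10771303 UMIs), classical-monocyte-like 2070 (50 to 235, 717472 to 4548448 UMIs), T-cell-like 4466 (135 to 607, 1371288 to 5938693 UMIs), B-cell-like 4641 (105 to 795, 742232 to 5477362 UMIs) and NK-cell-like 2536 (64 to 376, 562691 to 2605519 UMIs). A pool with few UMIs gives wide errors for genes at low CPM, and the standard error beside each log2 change carries this. Genes were filtered with filterByExpr and tested in edgeR 4.0.16 (TMM, quasi-likelihood, 1 fit per class with a mean for each of the 4 groups), with Benjamini-Hochberg adjustment within class and contrast and a threshold of adjusted p < 0.05. The 5 contrasts are irradiated minus unirradiated for each tumor genotype, AREG-KO minus AREG-sufficient for each irradiation state, and their interaction. CPM of named genes are scaled by TMM; those of Areg and Egfr by cell type are not. Shares of cells were compared with exact two-sided permutation tests over the pools.

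The 20 gene lists (EGFR ligands and receptors, type I interferon, interferon gamma, MHC class I and class II presentation, myeloid suppression, neutrophil granules, NF-kB and inflammatory cytokines, phagocytosis receptors, alternative activation, checkpoints, cytotoxic effectors, naive and central memory genes, chemokine receptors and adhesion, p53 targets, immediate early genes, hypoxia and glycolysis, TGF-beta signalling, cell cycle and oxidative phosphorylation) were fixed before the data were examined. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 475 tests, and again with the correlation estimated from the pools. A list count "adjusted over the list alone" uses Benjamini-Hochberg over the members of that list. Named genes follow a rule fixed before the data were examined: per main class and contrast, the 4 largest rises and 4 largest falls among called genes with a mean of at least 20 CPM, Areg and Egfr, and up to 4 members of each list by p, with predicted, mitochondrial, ribosomal and receptor segment genes skipped. For B-cell-like and NK-cell-like cells the limit is 3 each way. Of the genes so chosen, the text names a part.

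The pipeline was tested on data simulated at the pools' depths. At true log2 changes of 0.5, 1 and 2 it recovered 32.8, 75.8 and 98.5% of changed genes in neutrophil-like, 30.8, 80.3 and 96.9% in classical-monocyte-like and 38.5, 80 and 98.5% in T-cell-like cells. False calls were 4.26, 5.59 and 5.33% of calls, and none arose in the contrast with no simulated change. Camera called the changed list in each class and none of 40 unchanged lists. Free RNA was estimated per pool from B and T cell genes that the class should lack, a set revised after seeing the data. Alternatives fixed before the data were examined were DESeq2 1.42.0, no filter on low counts, leaving out each pool in turn, hashtag number as a replicate block, doublets kept, at least 1000 UMIs per cell, only the groups of the contrast in the fit, stricter hashtag assignment (the top hashtag at least 10 times the second), removal of genes that free RNA could bring, shares of cells outside the neutrophil-like class and Leiden resolution 2. Alternatives chosen after seeing the data were subtraction of the free RNA estimate, leaving out the 3 pools with many Rag1-positive cells, and shares without those cells. Pool pairs within groups had chi-square per degree of freedom of 1.49 to 23.1, so none are copies.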

Results

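Mice carried Lewis lung carcinoma, a mouse lung tumor line, in the flank, and the tumor cells were either able to make amphiregulin (AREG), an epidermal growth factor receptor ligand, or knocked out for it. The flank tumor was irradiated with 20 Gy on day 12 or left unirradiated, and live CD45-positive (leukocyte) cells were sorted from the lung, the site of metastasis, 5 days later. The 4 combinations of tumor genotype and irradiation were each profiled as 1 droplet library of single-cell transcripts with a matching hashtag library, in which 4 hashtag antibodies marked the cells. Hashtags divided each library into 4 pools of cells, so that each group had n = 4 pools. The labels do not say what a hashtag marks, so the p-values measure only the spread between hashtag pools, and each group is 1 lane, so lane and group cannot be told apart. The unirradiated AREG-sufficient library held 9365 barcodes and 57256017 unique molecular identifiers (UMIs), the irradiated AREG-sufficient library 8727 and 87335747, the unirradiated AREG-KO library 9782 and 85396778, and the irradiated AREG-KO library 10447 and 92089232. In the unirradiated AREG-sufficient library 40.9% of barcodes carried no hashtag, against 0.413, 0.552 and 0.689% in the others, and these were left out. After filtering, 5042, 7718, 8671 and 9121 cells remained in the same order.

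Areg itself (chromosome 5, 91139599 to 91148432, plus strand, a protein-coding gene) was measured first. The knockout was in the tumor cells, which the CD45 gate leaves out, so Areg transcripts in these lung leukocytes do not check the label. Over all kept cells Areg stood at 42.4 ± 12.9 CPM (counts scaled to 1000000; SD, n = 4) in the unirradiated and 50.2 ± 17.3 in the irradiated AREG-sufficient library, and at 27.8 ± 3.95 and 27.3 ± 12.1 in the AREG-KO libraries. The highest levels lay in ILC2-like cells, a tissue lymphocyte type, with 1452 ± 2206, 796 ± 858, 339 ± 302 and 443 ± 296 CPM in the same order. The first of these means rests on hashtag pool 1, where a single ILC2-like cell gave 4738 CPM, and UMIs summed over the 4 pools gave 538, 753, 412 and 398 CPM. Alveolar-macrophage-like cells had 300 ± 94.1, 239 ± 136, 139 ± 73.8 and 88.9 ± 56.6 CPM. Interstitial-macrophage-like cells, 19 to 47 per library, had 113 ± 107 over 3 pools, then 58 ± 116, 330 ± 386 and 187 ± 359 CPM, and UMIs summed over the pools gave 143, 101, 255 and 104 CPM. Among neutrophil-like cells 4.1, 5.89, 2.6 and 2.54% had an Areg UMI, against 0.309, 1.22, 0.292 and 0.704% of B-cell-like cells, which are not a known source and were of similar depth (median 6027, 6761, 5479 and 5159 UMIs in neutrophil-like and 6891, 6454, 6194 and 6224 in B-cell-like cells). In neutrophil-like cells the log2 difference of Areg was 0.66 ± 0.53 with irradiation of AREG-sufficient tumors (edgeR, adjusted p = 0.591), -0.29 ± 0.58 with irradiation of AREG-KO tumors (adjusted p = 0.932), -1.52 ± 0.54 between AREG-KO and AREG-sufficient tumors after irradiation (adjusted p = 0.0873) and -0.58 ± 0.57 without it (adjusted p = 0.922), and none passed the test. Egfr, its receptor, stood at 1.13 ± 0.837, 0.576 ± 0.269, 1.03 ± 0.656 and 1.29 ± 0.365 CPM over all cells, and its highest levels were in plasmacytoid-dendritic-like cells (13.5 ± 10.9, 29.7 ± 3.05, 28.4 ± 26.8 and 44.6 ± 21.4 CPM) and interstitial-macrophage-like cells (9.1 ± 7.96 over the 3 pools that had such cells, then 32.4 ± 64.9, 51.1 ± 56.8 and 24.5 ± 32.3 CPM). The list of EGFR ligands and receptors, with 3 members measured in neutrophil-like cells and as many in T-cell-like cells, had no member past the test, also when adjusted over the list alone except 1 of the 3 in irradiated AREG-KO against AREG-sufficient neutrophil-like cells, and the smallest of its adjusted p was 0.344 (or 0.557 with an estimated correlation).

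The composition of the lung leukocytes was compared next. Neutrophil-like cells, recognised by S100a8, S100a9, Retnlg and Csf3r, made up 40.6 ± 5.2% of the kept cells per pool (SD, n = 4) with unirradiated AREG-sufficient tumors and 56.8 ± 5.98% after irradiation, and each of the 4 irradiated pools lay above each of the 4 unirradiated ones (exact two-sided permutation test, p = 0.0286, the smallest p that 4 against 4 pools allow; adjusted over 12 comparisons 0.229). With the Rag1-positive cells described later out of the denominator the pools overlapped. The rise was then 13.1 points, or 15.8 without the 3 pools rich in them (both exact p = 0.0571). With AREG-KO tumors the shares were 30.6 ± 15% and 34.1 ± 18.9% (exact p = 0.83, adjusted 0.83). Between AREG-KO and AREG-sufficient tumors the neutrophil-like share differed by -22.6 percentage points after irradiation (exact p = 0.114) and by -10 without it (exact p = 0.257). Classical-monocyte-like cells (Ly6c2, Ccr2, Vcan) were 6.8 ± 1.82% and 8.92 ± 1.41% of cells with AREG-sufficient tumors (exact p = 0.114) and 5.54 ± 1.98% and 5.99 ± 1.14% with AREG-KO tumors (exact p = 0.743), and the 2 tumor genotypes differed with exact p = 0.0571 after irradiation and 0.4 without it. T-cell-like cells (Cd3e, Trac, Trbc2) were 12.6 ± 1.12% and 10.5 ± 2.46% with AREG-sufficient tumors (exact p = 0.171) and 19.2 ± 7.36% and 15.1 ± 3.32% with AREG-KO tumors (exact p = 0.4), with exact p = 0.0857 between the genotypes after irradiation and 0.0571 without it. None of these shares passed the threshold after Benjamini-Hochberg adjustment over the 12 comparisons. The sort, the tissue digestion and the exclusion of barcodes without a hashtag can each set these shares, and a class that grows lowers the share of the others. Clusters high in Rag1 and Dntt, genes of developing lymphocytes, were left unnamed, 2 of the 3 by the fixed marker rules and the smallest by a threshold set after seeing the data. They held 0.236 to 23.5% of cells over the pools of the unirradiated and 0.0887 to 0.331% over those of the irradiated AREG-sufficient library, and 0.197 to 0.38% and 0.931 to 30.8% in the AREG-KO libraries. Most of these cells lay in hashtag pool 2 of the unirradiated AREG-sufficient library and in pools 1 and 2 of the irradiated AREG-KO library, and the count of called genes in each main class and contrast is also given without these 3 pools.

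**Figure D1:**
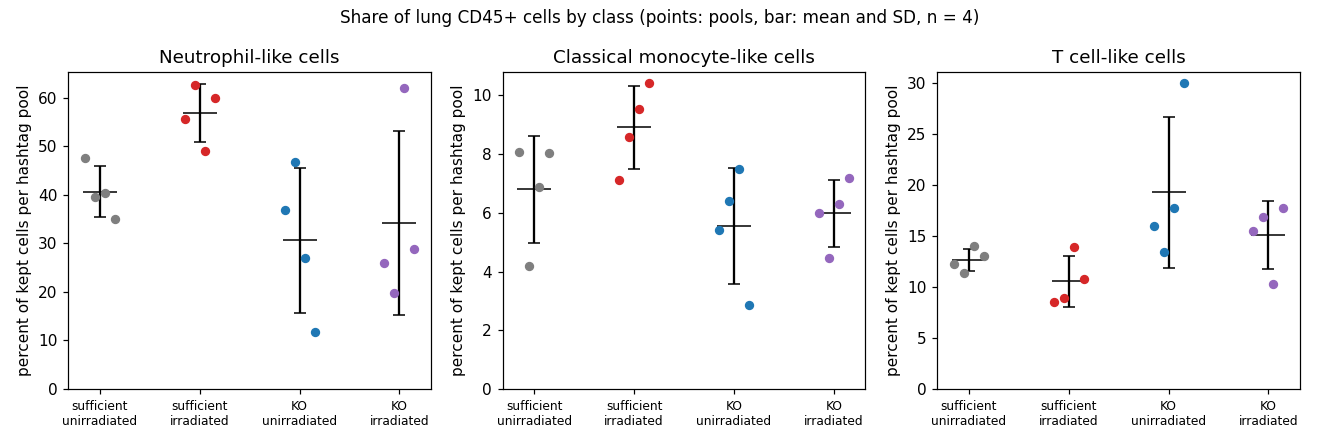
Percent of kept lung CD45-positive cells per hashtag pool that were neutrophil-like, classical-monocyte-like or T-cell-like (y axis) in the 4 groups (x axis); points are pools, and bars give the mean and SD over n = 4 pools. The 4 irradiated AREG-sufficient pools held 48.9 to 62.6% neutrophil-like cells, above the 35 to 47.6% of the unirradiated AREG-sufficient pools, and the AREG-KO pools spread widely. With Rag1-positive cells out of the denominator the pools of these 2 groups overlapped (exact p = 0.0571).

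Irradiation of AREG-sufficient tumors asks what irradiating the flank does to lung leukocytes when the tumor can make amphiregulin. In neutrophil-like cells 5 of 17 type I interferon genes fell, and 3 stefin A genes, which encode cysteine protease inhibitors of neutrophils, rose. Ifit3, an antiviral interferon-induced gene, went from 111 ± 55.9 to 26.5 ± 20.4 CPM (SD, n = 4), and Cstdc5 of the stefin A cluster from 22 ± 5.28 to 132 ± 85.9 CPM. S100a8, a subunit of calprotectin and one of the most abundant neutrophil transcripts, rose from 47480 ± 5747 to 85830 ± 15200 CPM. The quasi-likelihood test of edgeR called 144 of 8519 genes, 96 higher and 48 lower (log2 changes in parentheses, here and in what follows, are ± SE). Of 17 measured genes of the type I interferon list 5 fell over all genes tested and 15 when adjusted over the list alone, among them Ifit3 (-2.08 ± 0.48), Ifit1 (-1.40 ± 0.30), Slfn5 (-1.18 ± 0.26) and Zbp1 (-0.75 ± 0.16) (adjusted p from 0.0255 to 0.0328), with Ifit3b (-1.88 ± 0.46) and Stat1 (-0.57 ± 0.15) also lower, Stat1 being the transcription factor of interferon signalling. With median -0.75, that list gave adjusted p = 8.3e-15, or 0.193 with an estimated correlation. Nlrc5, the activator of MHC class I genes, fell by 1.28 on the log2 scale (adjusted p = 0.0018); it was the only called member of the 11 measured MHC class I genes (2 adjusted over the list alone; median -0.09, mean -0.25, adjusted p = 0.00761, or adjusted p = 0.406 with an estimated correlation). The interferon gamma list had 1 of 12 members lower (5 adjusted over the list alone). With median -0.43, that list gave adjusted p = 7.0e-05, or 0.164 with an estimated correlation. On the other side stood Cstdc5 (2.61 ± 0.49), Stfa3 (2.43 ± 0.57) and Cstdc4 (1.13 ± 0.25), with Crip1, a LIM-domain protein gene (1.09 ± 0.13). Crip1 is among the genes that free RNA could bring to these cells. The stefin genes lie side by side on chromosome 16 (Cstdc4 at 36184212 to 36188111, Cstdc5 at 36359382 to 36367748, Stfa3 at 36450537 to 36455392) and are similar in sequence, as Ifit3 (chromosome 19, 34583531 to 34588731) and Ifit3b (34607970 to 34613401) are, so their individual values are uncertain. Of 16 hypoxia and glycolysis genes 1 rose, the glycolytic enzyme gene Pgam1 (0.68 ± 0.15), or 9 adjusted over the list alone. At median 0.47, the list had adjusted p = 2.9e-06, or adjusted p = 0.269 with an estimated correlation. Oxidative phosphorylation had 5 of 17 members higher (13 adjusted over the list alone), among them Cox6c (0.59 ± 0.12) and Atp5l (0.45 ± 0.08), subunits of cytochrome oxidase and ATP synthase. With median 0.41, that list gave adjusted p = 2.0e-13, or adjusted p = 0.116 with an estimated correlation. The myeloid suppression list, of genes linked to suppressor myeloid cells, held 1 called gene of 21, S100a8 (0.85 ± 0.16), or 2 adjusted over the list alone. At median 0.11, the list had adjusted p = 0.0287, or adjusted p = 0.591 with an estimated correlation. No member of the cell cycle list (9 measured, 4 lower adjusted over the list alone; median -1.22, adjusted p = 0.0111, or adjusted p = 0.534 with an estimated correlation) or of the cytotoxic effector list (6 measured, 1 lower adjusted over the list alone; median -0.43, adjusted p = 0.0446, or adjusted p = 0.45 with an estimated correlation) passed over all genes. The neutrophil-like cells were spread over the clusters differently in the 2 groups: an interferon-gene-led cluster held 11.4 to 34.7% of them per unirradiated and 4.47 to 17.2% per irradiated pool, and a cluster led by Retnlg, Ly6g and stefin genes 5.39 to 19.3% and 16.8 to 47.8%. Without the 3 pools rich in Rag1-positive cells the count was 49, with Nlrc5, Cstdc5 and S100a8 still past the test and Ifit3, Ifit1, Slfn5, Zbp1 and Stat1 not, and with an estimate of free RNA subtracted it was 58; both alternatives were chosen after seeing the data.

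In classical-monocyte-like cells 3 of 19 type I interferon genes fell after irradiation of AREG-sufficient tumors. Irf7, a master regulator of type I interferon, went from 253 ± 96.5 to 124 ± 28.9 CPM and the neutrophil gene Wfdc21 from 16.1 ± 9.59 to 134 ± 101 CPM. In all, 287 of 9185 genes changed, 194 higher and 93 lower. The type I interferon list had 3 of 19 members lower (13 adjusted over the list alone): Irf7 (-0.99 ± 0.24), Slfn5 (-0.67 ± 0.17) and Oas1a (-0.53 ± 0.13). With median -0.67, that list gave adjusted p = 2.1e-10, or adjusted p = 0.292 with an estimated correlation. B2m and H2-D1, the light chain and a heavy chain of MHC class I, fell (-0.35 ± 0.09 and -0.32 ± 0.08) and were the 2 called of 11 MHC class I genes (5 adjusted over the list alone). At median -0.32, the list had adjusted p = 1.7e-05, or adjusted p = 0.224 with an estimated correlation. The largest other falls were Spon1 (-1.55 ± 0.39), Ifi213 (-1.25 ± 0.33) and Pde7b (-1.07 ± 0.20), Ifi213 being an interferon-inducible gene. The largest rises were Wfdc21 (3.02 ± 0.56), Lrg1 (2.48 ± 0.58), S100a8 (2.13 ± 0.37) and Retnlg (1.95 ± 0.20) (adjusted p from 1.5e-05 to 0.019), all abundant in neutrophils. Matrix metalloproteinase genes of neutrophil granules, Mmp8 (0.86 ± 0.20) and Mmp9 (1.36 ± 0.34), were the 2 called of 9 granule genes (2 adjusted over the list alone). With median 0.75, that list gave adjusted p = 0.00594, or adjusted p = 0.167 with an estimated correlation. The myeloid suppression list had 4 of 20 members higher (4 adjusted over the list alone; median 0.04, mean 0.21, adjusted p = 0.0446, or adjusted p = 0.415 with an estimated correlation). S100a8 and S100a9 took 0.192% of these cells' UMIs in the irradiated AREG-sufficient library (T-cell-like cells 0.197%), so free RNA remains possible. The share was 0.0501, 0.0668 and 0.07% in the unirradiated AREG-sufficient, unirradiated AREG-KO and irradiated AREG-KO libraries. Oxidative phosphorylation genes rose broadly, 11 of 17 (15 adjusted over the list alone), with Cox6c (0.49 ± 0.07) and Atp5e (0.44 ± 0.06) among them (median 0.39, adjusted p = 6.9e-23, and adjusted p = 0.0195 with an estimated correlation). With the 3 pools left out, the count was 189, and none of the interferon or MHC class I genes named here passed the test there.

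In T-cell-like cells the genes that rose most after irradiation of AREG-sufficient tumors were transcripts of neutrophils and other myeloid cells: Wfdc17 (2.49 ± 0.18), S100a8 (1.91 ± 0.19), Ifitm1 (1.84 ± 0.16) and S100a9 (1.82 ± 0.20) (adjusted p from 9.2e-09 to 3.6e-06). S100a8 went from 200 ± 66.3 to 753 ± 269 CPM, and S100a8 with S100a9 took 0.197% of the UMIs of T-cell-like, 0.204% of B-cell-like and 0.187% of NK-cell-like cells in this library, against 0.0571, 0.0592 and 0.0512% in the unirradiated one. Counts were 393 of 10011 genes, 287 higher and 106 lower. Myeloid suppression genes (13 of 18 higher, 14 adjusted over the list alone; median 1.35, adjusted p = 7.8e-44, and 7.0e-04 with an estimated correlation) and neutrophil granule genes (4 of 6 higher, 4 adjusted over the list alone; median 1.33, adjusted p = 8.2e-09, and 0.0323 with an estimated correlation) moved with these transcripts. So did the NF-kB and inflammatory cytokine list, where 3 of 11 rose (5 adjusted over the list alone), Il1b, the inflammasome cytokine, by 1.33 ± 0.12 (median 0.22, adjusted p = 4.8e-05, and 0.0365 with an estimated correlation). With free RNA subtracted the myeloid suppression list lost its call (11 of 18 members still measured; median 1.03, adjusted p = 0.528), as the NF-kB list did (7 of 11; median -0.07, adjusted p = 0.964). Members too low in counts after subtraction were not tested. Klf2, a transcription factor of quiescent T cells (0.40 ± 0.08), Dapl1 (0.50 ± 0.12) and Tcf7, a factor of naive and memory T cells (0.25 ± 0.07), rose and were the 3 called of 9 naive and central memory genes (3 adjusted over the list alone). At median 0.14, the list had adjusted p = 0.0235, or 0.373 with an estimated correlation. Tgfbr2, a TGF-beta receptor, fell by 0.35 on the log2 scale (adjusted p = 3.6e-04); its list had 1 member up and 1 down of 7 (1 and 3 adjusted over the list alone), with a median of -0.25, a mean of 0.04 and a test on the lower side (adjusted p = 0.0126, or adjusted p = 0.197 with an estimated correlation). Immediate early genes, which also answer tissue dissociation, had 3 of 18 higher (10 adjusted over the list alone), Jund among them (0.28 ± 0.07). With median 0.29, that list gave adjusted p = 2.7e-07, or 0.0667 with an estimated correlation. The phagocytosis receptor list (1 of 7 higher, 2 adjusted over the list alone; median 0.38, adjusted p = 0.0127, or adjusted p = 0.0929 with an estimated correlation) also moved. Oxidative phosphorylation had 13 of 17 genes higher (15 adjusted over the list alone), such as Ndufa2 of complex I (0.49 ± 0.07; median 0.34, adjusted p = 6.4e-20, and 0.0195 with an estimated correlation). The largest falls were Pxdc1 (-1.51 ± 0.38), Fanci (-0.80 ± 0.20), Fhit (-0.77 ± 0.14) and Adam9 (-0.76 ± 0.16), Fanci being a DNA repair gene. The count was 231 with free RNA subtracted and 287 without the 3 pools.

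**Figure D2:**
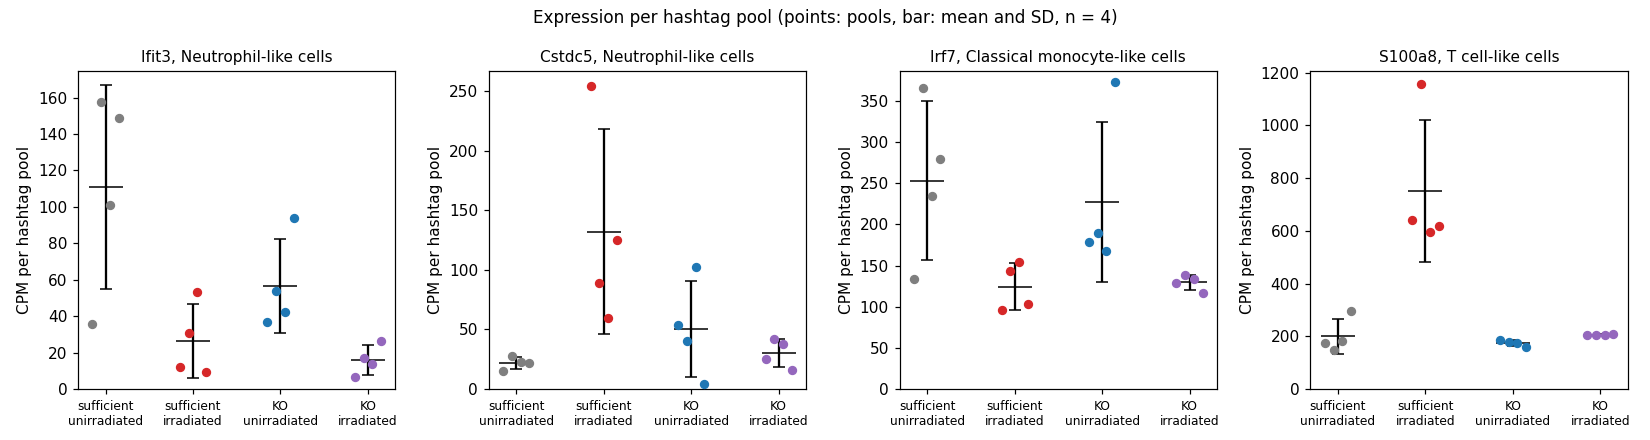
CPM per hashtag pool (y axis, linear) of Ifit3 and Cstdc5 in neutrophil-like, Irf7 in classical-monocyte-like and S100a8 in T-cell-like cells in the 4 groups (x axis); points are pools, and bars give the mean and SD over n = 4 pools. Ifit3 stood at 111 ± 55.9 CPM in unirradiated and 26.5 ± 20.4 CPM in irradiated AREG-sufficient pools, and S100a8 in T-cell-like cells at 200 ± 66.3 and 753 ± 269 CPM.

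Irradiation of AREG-KO tumors asks the same without amphiregulin from the tumor. Of the type I interferon genes only Oas1a, an interferon-induced sensor of double-stranded RNA, passed the test in the 2 myeloid classes here: in neutrophil-like cells it went from 31.3 ± 6.28 to 14.9 ± 2.88 CPM (SD, n = 4), and in classical-monocyte-like cells from 82.4 ± 17.2 to 43.7 ± 2.92 CPM. The MHC class II gene H2-Aa fell in neutrophil-like cells, and fewer single genes passed the test than with AREG-sufficient tumors. In neutrophil-like cells edgeR called 26 of 8519 genes (9 higher, 17 lower). Of 17 type I interferon genes 1 fell, Oas1a (-0.98 ± 0.18, adjusted p = 0.0184), or 9 adjusted over the list alone. At median -0.71, the list had adjusted p = 4.3e-16, or 0.172 with an estimated correlation. H2-Aa, an MHC class II chain, fell (-0.65 ± 0.13), the 1 called of 8 class II genes (6 adjusted over the list alone; median -0.48, adjusted p = 1.1e-08, and 0.0267 with an estimated correlation). Class II transcripts belong to B cells and antigen-presenting cells, and the B-cell-like share stood at 24.1 ± 10.2% of cells without and 13.9 ± 5.28% with irradiation, so free RNA remains possible. With free RNA subtracted H2-Aa did not pass (-0.95), while the list did (5 measured; median -0.52, adjusted p = 0.00472). The interferon-gene-led cluster held 9.14 to 20.3% of these cells per unirradiated and 4.73 to 8.21% per irradiated pool, so shifts between clusters and changes within them are not separated here. Psmb8, an immunoproteasome subunit, fell (-0.52 ± 0.11), 1 of 11 MHC class I presentation genes (5 adjusted over the list alone). At median -0.17, the list had adjusted p = 3.2e-04, or 0.246 with an estimated correlation. The interferon gamma list (12 measured; median -0.22, adjusted p = 0.0077, or adjusted p = 0.292 with an estimated correlation) and oxidative phosphorylation (17 measured; median -0.18, adjusted p = 8.3e-04, or adjusted p = 0.485 with an estimated correlation) were lower as lists with no called member, also when adjusted over the list alone. Camk1d, a calcium-dependent kinase, and Cdk8, a mediator kinase, rose (0.40 ± 0.07 and 0.39 ± 0.08), while AY036118 and Tmsb10, an actin-binding thymosin, fell (-0.68 ± 0.08 and -0.67 ± 0.14). Tmsb10 shares sequence with pseudogenes, so its counts are uncertain, and free RNA could bring it. Only 8 genes passed without the 3 pools, AY036118 alone of those named here, and 11 with free RNA subtracted.

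In classical-monocyte-like cells 7 of 9185 genes changed: Camk1d (0.51 ± 0.06) and Cdk8 (0.47 ± 0.07) were higher, and Oas1a (-0.88 ± 0.14), AY036118 (-0.69 ± 0.07) and Plac8 (-0.52 ± 0.07) lower (adjusted p from 1.9e-05 to 0.006). Type I interferon genes fell as a list, with 1 of 19 called (5 adjusted over the list alone). With median -0.58, that list gave adjusted p = 1.9e-14, or 0.212 with an estimated correlation. MHC class I genes were lower (11 measured, none called; median -0.18, adjusted p = 0.00129, or adjusted p = 0.363 with an estimated correlation) and NF-kB and inflammatory genes higher as a list (16 measured, none called, 1 adjusted over the list alone). At median 0.25, the list had adjusted p = 7.0e-05, or 0.217 with an estimated correlation. T-cell-like cells had 79 of 10011 genes called, 21 higher and 58 lower. Higher were Cxcl2, a neutrophil chemoattractant of myeloid cells (0.71 ± 0.16), Rab27a, needed for granule release (0.66 ± 0.14), Ifitm1 (0.62 ± 0.15) and Rgs1, a regulator of chemokine receptor signalling (0.57 ± 0.13). Lower were Gstp1 (-1.12 ± 0.16), AY036118 (-0.61 ± 0.06), Uba52 (-0.57 ± 0.06) and Rpa3 (-0.51 ± 0.12), Uba52 being a ubiquitin-ribosomal fusion gene with pseudogene copies. MHC class II genes, which mark other cells than T cells, were lower as a list with no called member of 8 (4 adjusted over the list alone; median -0.84, adjusted p = 1.9e-04, or adjusted p = 0.292 with an estimated correlation), and the myeloid suppression list was higher with 1 of 18 (3 adjusted over the list alone). With median 0.36, that list gave adjusted p = 4.5e-08, or 0.116 with an estimated correlation. Oxidative phosphorylation was lower (17 measured, none called, 1 adjusted over the list alone). At median -0.12, the list had adjusted p = 1.5e-06, or 0.167 with an estimated correlation. Leaving those 3 pools out, the counts were 3 in classical-monocyte-like and 9 in T-cell-like cells, the latter 33 with free RNA subtracted. Of the genes named here AY036118 and Camk1d still passed without these pools in classical-monocyte-like and AY036118, Gstp1 and Uba52 in T-cell-like cells.

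After irradiation, 3 stefin A genes, S100a8, S100a9 and 5 of 16 hypoxia and glycolysis genes were lower in lung neutrophil-like cells from mice with AREG-KO tumors than with AREG-sufficient tumors. Cstdc5 stood at 30.3 ± 11.9 against 132 ± 85.9 CPM (SD, n = 4), S100a9 at 76600 ± 18260 against 113900 ± 15520 and Ldha, lactate dehydrogenase, at 144 ± 27.1 against 230 ± 36.8. The comparison asks what tumor amphiregulin changes in the irradiated setting. It gave 665 called genes of 8519, 320 higher and 345 lower with AREG-KO tumors. The largest falls were Stfa2 (-2.18 ± 0.52), Cstdc5 (-2.13 ± 0.47), Stfa3 (-1.86 ± 0.52) and Acvrl1 (-1.18 ± 0.33) (adjusted p from 0.0116 to 0.0341), Acvrl1 being a receptor of the TGF-beta family, and the largest rises Eml1 (1.43 ± 0.29), Dock4 (1.31 ± 0.29), Tns3 (1.31 ± 0.26) and Slc9a9 (1.15 ± 0.20) (adjusted p from 0.00296 to 0.0121), genes of the cytoskeleton, adhesion and ion exchange. Of 21 myeloid suppression genes 5 fell (7 adjusted over the list alone), S100a8 (-0.56 ± 0.15) and S100a9 (-0.57 ± 0.13) among them. With median -0.21, that list gave adjusted p = 0.00723, or 0.484 with an estimated correlation. Hypoxia and glycolysis had 5 of 16 lower (10 adjusted over the list alone), with Eno1 (-0.85 ± 0.18), Hk2 (-0.73 ± 0.18) and Ldha (-0.67 ± 0.14). Eno1 was called lower in all 5 classes, which a lane could give. At median -0.52, the list had adjusted p = 7.0e-06, or 0.276 with an estimated correlation. Type I interferon genes were lower in 2 of 17 (3 adjusted over the list alone), Oas1a (-1.07 ± 0.17) and Zbp1 (-0.75 ± 0.17), a sensor of viral nucleic acid. With median -0.40, that list gave adjusted p = 0.00345, or 0.661 with an estimated correlation. Ifitm3, an antiviral membrane gene, fell too (-0.89 ± 0.19). Oxidative phosphorylation had 3 of 17 lower (9 adjusted over the list alone). With median -0.29, that list gave adjusted p = 9.7e-06, or 0.332 with an estimated correlation. Lymphocyte transcripts were higher in these pools: Tcf7 of the naive and central memory list (1.46 ± 0.26; 3 of 8 called, 6 adjusted over the list alone; median 0.67, adjusted p = 3.6e-04, or adjusted p = 0.0761 with an estimated correlation) and the granzyme gene Gzma of the cytotoxic list (1.02 ± 0.22; 2 of 6 called, 4 adjusted over the list alone). At median 0.64, the list had adjusted p = 0.00247, or 0.246 with an estimated correlation. T cell checkpoint genes (1 of 7 called, 1 adjusted over the list alone; median 0.69, adjusted p = 0.00543, or adjusted p = 0.0628 with an estimated correlation) and cell cycle genes (9 measured, none called; median 0.86, adjusted p = 0.0167, or adjusted p = 0.557 with an estimated correlation) were also higher as lists. Free RNA remains possible for these lymphocyte transcripts, since T-cell-like (15.1 ± 3.32 against 10.5 ± 2.46%), B-cell-like (13.9 ± 5.28 against 8.6 ± 0.826%) and NK-cell-like cells (9.42 ± 4.18 against 6.29 ± 1.55%) had higher mean shares in the AREG-KO pools. Gzma is among the genes that free RNA could bring, and neither Gzma nor Tcf7 was left to test once free RNA was subtracted, which gave 406 called genes. The Retnlg-led neutrophil cluster held 3.49 to 22.9% of these cells per AREG-KO pool and 16.8 to 47.8% per AREG-sufficient pool. Without the 3 pools, 2 of them from the irradiated AREG-KO library, 72 genes were called, and of the genes named for this comparison only Oas1a and Gzma passed.

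Classical-monocyte-like cells had 98 of 9185 genes called between the irradiated groups (69 higher, 29 lower with AREG-KO tumors). Il6, an inflammatory cytokine, rose from 39.5 ± 5.68 to 70.8 ± 13.6 CPM (0.84 ± 0.18), and Tmcc3, Rasgef1b, Klf9, a glucocorticoid-responsive factor, and Irs2, an insulin receptor substrate, rose (1.24 ± 0.26, 1.06 ± 0.24, 0.98 ± 0.21 and 0.90 ± 0.19). The falls were led by Wfdc21 (-2.56 ± 0.50), Lrg1 (-2.17 ± 0.52), F11r (-1.82 ± 0.34) and S100a8 (-1.62 ± 0.35) (adjusted p from 0.0138 to 0.0461). Free RNA could bring S100a8. Neutrophil granule genes were lower as a list (9 measured, none called, 2 adjusted over the list alone; median -0.53, adjusted p = 0.00761, or adjusted p = 0.164 with an estimated correlation) and so was myeloid suppression (4 of 20 lower, 1 up and 5 down adjusted over the list alone). With median -0.12, that list gave adjusted p = 0.014, or 0.292 with an estimated correlation. Hypoxia and glycolysis had 1 member higher and 3 lower of 15 (2 and 6 adjusted over the list alone), Eno1, enolase, among the lower (-0.53 ± 0.10). At median -0.12, the list had adjusted p = 0.028, or adjusted p = 0.422 with an estimated correlation. T-cell-like cells had 289 of 10011 called, 97 higher and 192 lower. Neutrophil transcripts led the falls, Retnlg (-1.96 ± 0.16), S100a8 (-1.86 ± 0.18), S100a9 (-1.78 ± 0.20) and Wfdc17 (-1.73 ± 0.15), and the share of UMIs from S100a8 and S100a9 was 0.0583% against 0.197% in these cells. With them moved myeloid suppression (11 of 18 lower, 1 up and 15 down adjusted over the list alone; median -1.13, adjusted p = 5.0e-46, and 7.0e-04 with an estimated correlation, but 0.929 with free RNA subtracted, 11 members measured and a median of -0.26) and granule genes (4 of 6 lower, 1 up and 4 down adjusted over the list alone). With median -1.07, that list gave adjusted p = 4.5e-07, or adjusted p = 0.0543 with an estimated correlation. Nrp1, a semaphorin co-receptor (1.13 ± 0.24), Mdfic (0.83 ± 0.22), Mfhas1 (0.79 ± 0.13) and Coro2a (0.66 ± 0.18) rose most, and Il7r, the interleukin 7 receptor of naive and memory T cells, rose while Tcf7 fell (0.41 ± 0.11 and -0.33 ± 0.07). Immediate early genes were lower in 3 of 18 (8 adjusted over the list alone), Jund among them (-0.44 ± 0.07). At median -0.18, the list had adjusted p = 8.8e-06, or adjusted p = 0.123 with an estimated correlation. Cytotoxic effector genes were higher as a list (11 measured, none called, 2 adjusted over the list alone). With median 0.46, that list gave adjusted p = 0.00275, or adjusted p = 0.415 with an estimated correlation. With the 3 pools left out, the counts were 11 in classical-monocyte-like cells and 63 in T-cell-like cells, and with free RNA subtracted the T-cell-like count was 98. None of the classical-monocyte-like genes named here passed without these pools, and of the T-cell-like genes only Jund and the 4 neutrophil transcripts did.

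Without irradiation, the comparison of AREG-KO with AREG-sufficient tumors asks what tumor amphiregulin changes at baseline. Neutrophil-like cells had more MHC class II transcripts with AREG-KO tumors, Cd74, the invariant chain, at 117 ± 12.4 against 69.6 ± 7.58 CPM (SD, n = 4), and less Il31ra, a cytokine receptor chain, at 114 ± 8.34 against 203 ± 13.8 CPM. The number called was 43 of 8519 genes, 37 higher and 6 lower. Of 8 class II genes 3 rose (7 adjusted over the list alone), Cd74 (0.75 ± 0.11), H2-Aa (0.67 ± 0.13) and H2-Ab1 (0.67 ± 0.14) (median 0.71, adjusted p = 2.0e-15, and 0.007 with an estimated correlation). These genes belong to B cells and antigen-presenting cells, and with free RNA subtracted none of the 3 passed, at log2 changes of 0.90, 0.73 and 0.87, while the list still did (5 measured; median 0.81, adjusted p = 1.1e-04). Type I interferon genes were lower as a list with no called member of 17 (2 adjusted over the list alone; median -0.58, adjusted p = 4.6e-09, or adjusted p = 0.307 with an estimated correlation), and so were interferon gamma genes (12 measured, none called). At median -0.34, the list had adjusted p = 4.9e-04, or 0.205 with an estimated correlation. The interferon-gene-led cluster held 9.14 to 20.3% of these cells per AREG-KO and 11.4 to 34.7% per AREG-sufficient pool, so shifts between clusters and changes within them are not separated. Oxidative phosphorylation had 2 of 17 higher (3 adjusted over the list alone). With median 0.26, that list gave adjusted p = 6.1e-09, or 0.205 with an estimated correlation. The largest rises were Tmsb10 (0.99 ± 0.14), Uba52 (0.99 ± 0.12) and Crip1 (0.89 ± 0.14), and the falls Il31ra (-0.83 ± 0.09), Cmss1 (-0.70 ± 0.08) and Cdk8 (-0.46 ± 0.08) (adjusted p from 6.6e-05 to 0.0042). Tmsb10 and Crip1 are among the genes that free RNA could bring. Il31ra (chromosome 13, 112519898 to 112594360) was lower with AREG-KO tumors in all 5 classes, irradiated or not. Unirradiated, it changed by -0.64 ± 0.10 in classical-monocyte-like and -0.92 ± 0.07 in T-cell-like cells. A lane difference could give this. The count was 19 without the 3 pools, where Cd74 and Il31ra passed and H2-Aa and H2-Ab1 did not, and 16 with free RNA subtracted.

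Classical-monocyte-like cells had 55 of 9185 genes called between the unirradiated groups, 50 higher and 5 lower. They were led by Uba52 (1.03 ± 0.10), Ehmt1 (0.75 ± 0.17), Tmsb10 (0.58 ± 0.10) and Tmem258 (0.58 ± 0.09) on the higher side, Ehmt1 being a histone methyltransferase, and by Il31ra, Cmss1 (-0.52 ± 0.06) and Slc15a3, a lysosomal peptide transporter (-0.45 ± 0.10), on the lower. Oxidative phosphorylation was higher in 2 of 17 (8 adjusted over the list alone), with the ATP synthase subunit Atp5e at 770 ± 30 against 581 ± 16 CPM (0.41 ± 0.06). At median 0.21, the list had adjusted p = 4.5e-10, or 0.116 with an estimated correlation. In T-cell-like cells 260 of 10011 genes were called, 192 higher and 68 lower. Eomes, a transcription factor of cytotoxic and memory T cells, went from 35.5 ± 20.8 to 15.3 ± 6.04 CPM (-1.19 ± 0.31), and Sox4 (-1.01 ± 0.26) and Plxdc2 (-0.95 ± 0.23) fell too. Eomes rests in part on 1 pool. Without pool 1 of the AREG-sufficient library its change was -0.72 (adjusted p = 0.266). Smad7, the inhibitor of TGF-beta signalling (-0.51 ± 0.11), was the 1 called of 7 TGF-beta genes, with 5 lower adjusted over the list alone. At median -0.29, the list had adjusted p = 8.5e-05, or 0.0529 with an estimated correlation. Lgals3, galectin 3 (1.11 ± 0.23), Uba52 (1.12 ± 0.06), Fmc1, an ATP synthase assembly factor (0.79 ± 0.12), Polr2l, an RNA polymerase subunit (0.69 ± 0.16), and Dapl1 (0.62 ± 0.12) were higher. Oxidative phosphorylation had 11 of 17 higher (15 adjusted over the list alone), Ndufa2 among them (0.48 ± 0.06; median 0.32, adjusted p = 2.9e-23, and 0.0122 with an estimated correlation). Leaving those 3 pools out, the counts were 37 and 197.

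The interaction test (irradiation change in AREG-sufficient minus that in AREG-KO) called genes in each of the 3 classes, but each group is 1 lane. Of called genes measured in 5 classes, 87.9, 92.5 and 85.4% (neutrophil-like, classical-monocyte-like, T-cell-like) moved the same way in all, against 30.2% of all genes. In neutrophil-like cells 3 stefin A genes moved apart: Cstdc5 (3.44 ± 0.69), Stfa1 (2.00 ± 0.53) and Cstdc4 (1.61 ± 0.36), with Cstdc5 going from 22 ± 5.28 to 132 ± 85.9 CPM with AREG-sufficient and from 50.4 ± 40.6 to 30.3 ± 11.9 CPM with AREG-KO tumors (SD, n = 4). S100a8 (1.01 ± 0.22) and the glycolytic genes Eno1 (1.04 ± 0.25) and Pgam1 (0.97 ± 0.21) had interactions of the same sign. EdgeR called 215 of 8519 genes, 162 above and 53 below 0. Hypoxia and glycolysis had 2 of 16 called (8 adjusted over the list alone; median 0.66, adjusted p = 1.3e-05, or adjusted p = 0.292 with an estimated correlation), and oxidative phosphorylation 5 of 17 (15 adjusted over the list alone), such as Atp5l (0.66 ± 0.11). With median 0.51, that list gave adjusted p = 1.8e-12, or 0.14 with an estimated correlation. MHC class II presentation had 1 of 8 (4 adjusted over the list alone; median 0.55, adjusted p = 0.00174, or adjusted p = 0.196 with an estimated correlation) and myeloid suppression 1 of 21 (4 adjusted over the list alone). At median 0.22, the list had adjusted p = 0.0122, or 0.516 with an estimated correlation. Tmsb10 was above 0 (1.34 ± 0.19), and Borcs5 (-1.10 ± 0.24), Ergic1 (-1.09 ± 0.24), Pde4d (-1.04 ± 0.22) and Usp2 (-0.74 ± 0.18) were below (adjusted p from 0.0137 to 0.0261). No difference in the response of the type I interferon list was detected (median -0.23, adjusted p = 0.74), with no member called. Without the 3 pools 42 genes were called, Tmsb10 alone of those named here, and 122 with free RNA subtracted.

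Classical-monocyte-like cells had 95 called interactions of 9185 genes (79 above, 16 below 0). Above 0 were S100a9 (1.97 ± 0.37), Retnlg (1.70 ± 0.29), Ifitm1 (1.00 ± 0.23) and Uba52 (0.93 ± 0.14). Below it were Glis3 (-1.25 ± 0.28), Zbtb20 (-0.84 ± 0.19), Aff1 (-0.84 ± 0.13) and Dhx40 (-0.74 ± 0.18). Free RNA could bring S100a9, Retnlg and Ifitm1. Oxidative phosphorylation had 3 of 17 called (11 adjusted over the list alone; median 0.37, adjusted p = 8.2e-13, or adjusted p = 0.0667 with an estimated correlation), and the granule list none of 9. With median 0.50, that list gave adjusted p = 0.044, or 0.269 with an estimated correlation. In T-cell-like cells 476 of 10011 genes were called, 333 above and 143 below 0. The largest were again the neutrophil transcripts Wfdc17 (1.95 ± 0.24), Retnlg (1.89 ± 0.25), S100a8 (1.67 ± 0.26) and S100a9 (1.59 ± 0.28), with the myeloid suppression list (8 of 18 above 0, 11 above and 1 below adjusted over the list alone). With median 0.95, that list gave adjusted p = 4.1e-11, or 0.0537 with an estimated correlation. Among T cell genes Klf2 (0.52 ± 0.11) and Dapl1 (0.70 ± 0.16) were the 2 called of 9 naive and central memory genes (4 adjusted over the list alone; median 0.25, adjusted p = 0.0301, or adjusted p = 0.406 with an estimated correlation), while Mdfic (-1.17 ± 0.31), Fanci (-1.04 ± 0.26), Cdc14a (-1.04 ± 0.27) and Mfhas1 (-1.01 ± 0.18) were below 0. Jund (0.57 ± 0.09) was 1 called of 18 immediate early genes (6 adjusted over the list alone). At median 0.29, the list had adjusted p = 2.2e-04, or adjusted p = 0.193 with an estimated correlation. TGF-beta signalling had 1 of 7 below 0 (1 above and 5 below adjusted over the list alone; median -0.35, mean -0.08, adjusted p = 0.00622, or adjusted p = 0.167 with an estimated correlation). Oxidative phosphorylation had 15 of 17 above 0 (16 adjusted over the list alone; median 0.47, adjusted p = 2.0e-21, and 0.0166 with an estimated correlation). With the 3 pools left out, the counts were 18 and 260.

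Part of each oxidative phosphorylation median, except that of classical-monocyte-like cells with irradiation of AREG-KO tumors, was shared by genes of like length. Over genes matched on length and expression the median excess in neutrophil-like, classical-monocyte-like and T-cell-like cells was 0.13, 0.12 and 0.13 with irradiation of AREG-sufficient tumors and -0.04, 0.09 and -0.04 with AREG-KO tumors. Between genotypes it was -0.08, -0.01 and -0.02 after irradiation and 0.12, 0.10 and 0.17 without it, and for the interaction 0.20, 0.11 and 0.15. Matching also moved medians of other called lists by over 1.5 times, such as myeloid suppression in neutrophil-like cells (irradiation with AREG-sufficient tumors, 0.11 to 0.03; interaction, 0.22 to 0.11). In classical-monocyte-like cells that list moved from 0.04 to -0.10 with irradiation of AREG-sufficient tumors. Type I interferon in neutrophil-like cells moved from -0.40 to -0.26 between irradiated genotypes. In T-cell-like cells TGF-beta signalling moved from -0.35 to -0.21 in the interaction. Across the 20 lists, 5 classes and 5 contrasts, 149 of 475 list tests passed with the preset correlation and 36 of these also passed with an estimated one. In neutrophil-like, classical-monocyte-like and T-cell-like cells those were the oxidative phosphorylation, MHC class II, myeloid suppression, granule and NF-kB tests whose estimated p is under 0.05, with 1 more, hypoxia and glycolysis in T-cell-like cells between the irradiated groups (median -0.21, 1 up and 2 down of 15, 2 and 6 adjusted over the list alone; adjusted p = 6.5e-04, and 0.0267 with an estimated correlation). Chemokine receptor and adhesion genes, p53 targets and alternative activation genes gave no passing test in any class or contrast, with smallest adjusted p of 0.0525, 0.0658 and 0.0584.

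**Figure D3:**
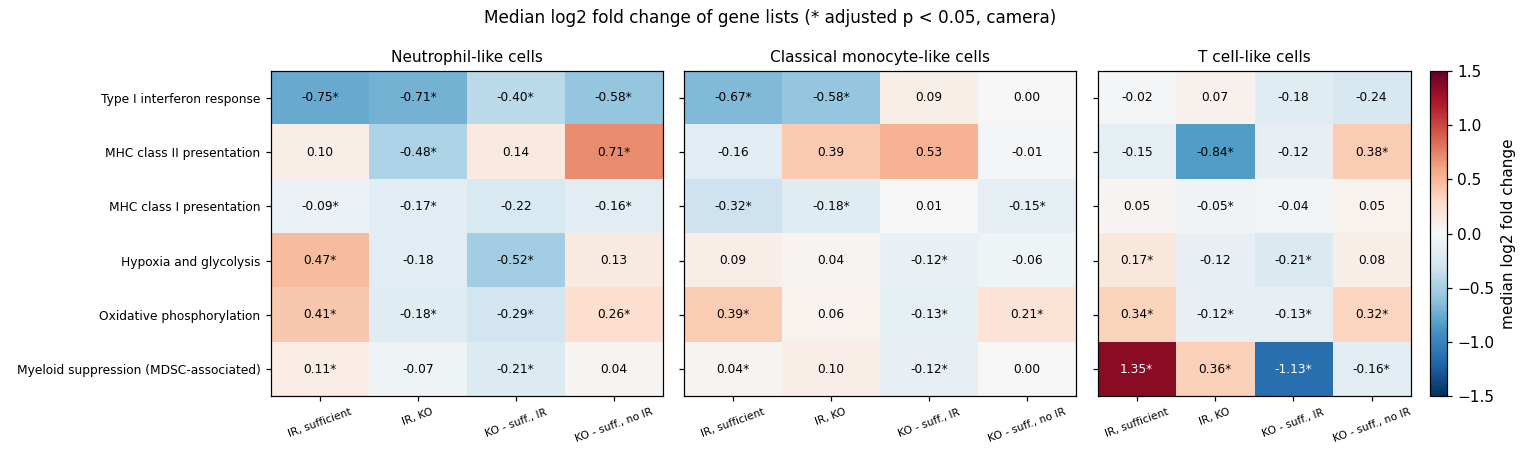
Median log2 fold change of 6 gene lists (rows) in 4 contrasts (columns) for neutrophil-like, classical-monocyte-like and T-cell-like cells; color and printed value give the median, and a star marks adjusted p under 0.05 in camera with its preset correlation. The type I interferon median was -0.75 and -0.71 with irradiation in neutrophil-like and -0.67 and -0.58 in classical-monocyte-like cells (AREG-sufficient, then AREG-KO), and none of these 4 passed with an estimated correlation (adjusted p = 0.193, 0.172, 0.292 and 0.212). The myeloid suppression median in T-cell-like cells was 1.35.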

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

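The tests of explanations in this part were chosen after the results they explain were seen, except transcript length for the respiratory chain genes and doublets for the neutrophil transcripts, whose predictions were written before their values were computed. The interaction test of edgeR (n = 4 pools per group, 1 lane each) called 215 genes in neutrophil-like, 95 in classical-monocyte-like and 476 in T-cell-like cells. In neutrophil-like cells these genes included Cstdc5 (3.44), Stfa1 (2.00), Cstdc4 (1.61) and, possibly from free RNA, Tmsb10 (1.34). Below 0 were Borcs5 (-1.10), Ergic1 (-1.09), Pde4d (-1.04) and Usp2 (-0.74). From the lists came S100a8 (1.01), Eno1 (1.04), Pgam1 (0.97) and Atp5l (0.66). In classical-monocyte-like cells S100a9 (1.97), Retnlg (1.70), Ifitm1 (1.00) and Uba52 (0.93) were above 0. Glis3 (-1.25), Zbtb20 (-0.84), Aff1 (-0.84) and Dhx40 (-0.74) were below it. In T-cell-like cells Wfdc17 (1.95), Retnlg (1.89), S100a8 (1.67) and S100a9 (1.59) were above 0. Mdfic (-1.17), Fanci (-1.04), Cdc14a (-1.04) and Mfhas1 (-1.01) were below it. Klf2 (0.52), Dapl1 (0.70) and Jund (0.57) came from the lists. Leaving out 1 pool moved these counts to 131 to 404, 45 to 139 and 344 to 497. The lowest came without pool 1 of the irradiated AREG-KO library (neutrophil-like) and without pool 4 of the unirradiated AREG-sufficient library (classical-monocyte-like).

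The same interaction was called for 12 of the list tests named in the text, of which only oxidative phosphorylation in T-cell-like cells kept its call with an estimated correlation (adjusted p = 0.0166). The medians in neutrophil-like cells were 0.55 for MHC class II presentation, 0.22 for myeloid suppression, 0.66 for hypoxia and glycolysis and 0.51 for oxidative phosphorylation. In classical-monocyte-like cells they were 0.37 for oxidative phosphorylation and 0.50 for neutrophil granules. In T-cell-like cells they were 0.95 for myeloid suppression, 1.25 for granules (3 of 6 members called above and 0 below 0; 4 and 1 adjusted over the list alone; adjusted p = 0.00811, or adjusted p = 0.269 with an estimated correlation), 0.25 for naive and central memory genes, 0.29 for immediate early genes, -0.35 for TGF-beta signalling and 0.47 for oxidative phosphorylation.

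Single pools lay far from the other 3 of their group (by Dixon's ratio of gap to range) in 28 of 386 groups of 4 values, where chance flags about 1 in 20 groups, or 19.3 here. In neutrophil-like cells they were Stfa3 at 120 CPM (others 23.6 to 35.5) in pool 1 and Ifitm3 at 1929 CPM (others 1439 to 1520) in pool 4 of the irradiated AREG-sufficient library, Cd74 at 98.7 CPM (others 121 to 125) in pool 3 and Pgam1 at 72.9 CPM (others 94.7 to 96.4) in pool 4 of the unirradiated AREG-KO library, and Usp2 at 25.4 CPM (others 21.3 to 21.9) in pool 3 of the unirradiated AREG-sufficient library. In classical-monocyte-like cells pool 4 of the irradiated AREG-sufficient library held Lrg1 at 245 CPM (others 44.4 to 59.5), S100a8 at 1380 CPM (others 753 to 794) and Ifitm1 at 147 CPM (others 95.9 to 104). Pool 2 of the unirradiated AREG-KO library held Camk1d at 1983 CPM (others 2090 to 2110) and S100a9 at 778 CPM (others 255 to 324), and its pool 1 Plac8 at 3609 CPM (others 4195 to 4274). Pool 2 of the unirradiated AREG-sufficient library held Uba52 at 99.3 CPM (others 141 to 146) and S100a9 at 418 CPM (others 231 to 238), and pool 3 of the irradiated AREG-KO library Wfdc21 at 55.2 CPM (others 10.8 to 11.5). In T-cell-like cells pool 2 of the irradiated AREG-sufficient library held Wfdc17 at 134 CPM (others 87 to 90), S100a8 at 1156 CPM (others 597 to 642) and S100a9 at 1959 CPM (others 1050 to 1057), and its pool 3 Mfhas1 at 83 CPM (others 68.2 to 69.9). Pool 4 of the unirradiated AREG-sufficient library held Ifitm1 at 41.1 CPM (others 20.4 to 23.3), S100a9 at 589 CPM (others 271 to 300) and Retnlg at 55.4 CPM (others 24.7 to 25.6), and its pool 3 Wfdc17 at 13.2 CPM (others 19.1 to 19.8). Pool 2 of the unirradiated AREG-KO library held AY036118 at 507 CPM (others 474 to 476) and Mfhas1 at 74.9 CPM (others 96.5 to 100), and pool 3 of the irradiated AREG-KO library Dapl1 at 230 CPM (others 168 to 175). Clec4e stood at 26.2 CPM (others 20.2 to 20.4) in B-cell-like cells of pool 2 of the irradiated AREG-KO library, Ulk1 at 6.64 CPM (others 13.8 to 15) in NK-cell-like cells of pool 1 of the unirradiated AREG-KO library and Rgs16 at 59 CPM (others 15.3 to 20.9) in those of pool 1 of the irradiated AREG-sufficient library.

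Data outside the comparisons also held signals. Barcodes with no hashtag made up 40.9% of the unirradiated AREG-sufficient library, and 3607 of them held under 3000 UMIs (median 1077). Clusters high in Rag1 and Dntt, 1340 cells, made up 23.5% of cells in hashtag pool 2 of the unirradiated AREG-sufficient library. They made up 12.4 and 30.8% in pools 1 and 2 of the irradiated AREG-KO library.

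Those cells were weighed first. Of 12 thymocyte genes 10 were at least 2-fold higher in them than in T-cell-like cells, and 68.7% held both Cd4 and Cd8b1 transcripts (T-cell-like 2.22%), so thymus in the cell suspension fits. B-lineage progenitors are excluded, since Cd79a and Ebf1 reached at most 0.00588 of their B-cell-like level. An effect of irradiation or AREG status also met its prediction. All pools of the irradiated AREG-KO group lay above those of both groups compared with it (exact p = 0.0286). Pools overlapped for irradiation with AREG-sufficient tumors (exact p = 0.0571) and between unirradiated genotypes (exact p = 0.0857). In the unirradiated AREG-KO and irradiated AREG-sufficient libraries 1 dividing cluster gave 23 and 14 of the cells counted. At resolution 2 a dividing cluster with NK cell markers and 3.08 CPM of Rag1 and Dntt held as many. The separation thus does not measure cells high in these genes alone, so it decides nothing. The 3 pools over 10% lay in groups opposite in both factors, beside pools of 0.236 to 0.471% and 0.931 to 1.33%. This argues against either factor as their source, though 3 pools cannot exclude it.

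Of 17 respiratory chain genes 5 rose in neutrophil-like, 11 in classical-monocyte-like, 13 in T-cell-like, 5 in B-cell-like and 7 in NK-cell-like cells with irradiation of AREG-sufficient tumors. The list passed in all 5 classes, but not in neutrophil-like (adjusted p = 0.116) or B-cell-like cells (adjusted p = 0.0628) with an estimated correlation. Free RNA is undecided. Subtraction left at least 0.958 of the list median in neutrophil-like, classical-monocyte-like and T-cell-like cells, but took out few UMIs (group means 1.63 to 4.88%). B-cell-like and NK-cell-like cells were not tested for it. Transcript length bias fits: in 4 of 5 classes the excess over genes matched on length and expression was below 0.5 of the raw median, and log2 change and transcript length were negatively correlated in neutrophil-like cells (Spearman -0.253). A difference between lanes cannot be told from a response of the whole animal, since the list moved the same way in 5 of 5 classes under both.

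Neutrophil transcripts in T-cell-like cells were weighed last. Free RNA fits: the S100a8 and S100a9 share of UMIs differed between T-cell-like and B-cell-like cells by at most 1.34-fold in any library. Subtraction decides nothing here, as only 1 of 7 called neutrophil markers was still tested after it (log2 change 1.10). Doublets with neutrophils are excluded as the main source, because the top 5% of T-cell-like cells carried 24.5% of the neutrophil marker UMIs. A biological explanation was not tested, as no group separates cell uptake from free RNA.

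To test chance, the same pools were divided in every other way for all 15 counts (35 divisions, or 100 sampled for the interaction). In each only the real division reached the real count. Among 35 this is a share of 0.0286, unadjusted, so chance is less likely but not excluded. For neutrophil-like cells the real counts and the highest others were 144 and 8 for irradiation with AREG-sufficient tumors, 26 and 0 with AREG-KO tumors, 665 and 119 for AREG-KO against AREG-sufficient after irradiation, 43 and 1 without it, and 215 and 4 for the interaction. For classical-monocyte-like cells they were 287 and 4, 7 and 0, 98 and 64, 55 and 1, and 95 and 3 in that order, and for T-cell-like cells 393 and 4, 79 and 2, 289 and 1, 260 and 10, and 476 and 11. The divisions mix pools of 2 lanes, so they do not separate a lane from a group.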

How the results depend on the processing

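The subtraction of free RNA and both settings without the Rag1-positive pools or cells were chosen after seeing the data; the other settings were fixed before the data were examined. Counts are given in the order irradiation with AREG-sufficient tumors, irradiation with AREG-KO tumors, AREG-KO against AREG-sufficient irradiated, the same unirradiated, and interaction; those left out stayed within 1.5 times of the reported count. DESeq2 gave 330, 53, 73 (unirradiated) and 400 genes in neutrophil-like, 22, 240, 106 and 221 in classical-monocyte-like (all but the first) and 183 (irradiation, AREG-KO) in T-cell-like cells. Without the filter on low counts there were 531, 119, 1040, 94 and 478, then 496, 154, 428, 161 and 285, then 659, 264, 502 and 500 (all but the interaction). With only the groups of the contrast fitted, neutrophil-like cells gave 77, 8 and 17 (unirradiated), classical-monocyte-like 140 and 59 (irradiated) and T-cell-like 166 (unirradiated). With free RNA subtracted, neutrophil-like cells gave 58, 11, 406, 16 and 122 and T-cell-like 231, 33 and 98. Without the 3 Rag1-positive pools, which leaves fewer pools, they were 49, 8, 72, 19 and 42, then 189, 3, 11 and 18 (interaction), then 9, 63 and 260 (irradiation with AREG-KO, irradiated, interaction). The cause was not tested. Doublets kept, at least 1000 UMIs, strict hashtags and removal of free-RNA genes moved no count over 1.5 times.

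Leaving out 1 pool gave 39 to 227, 9 to 28, 208 to 1058, 22 to 52 and 131 to 404 genes in neutrophil-like, 128 to 367, 6 to 11, 22 to 159, 30 to 68 and 45 to 139 in classical-monocyte-like and 301 to 437, 23 to 105, 177 to 326, 198 to 278 and 344 to 497 in T-cell-like cells. Shares, in percentage points without the interaction, ranged over 14.2 to 18.8, -5.74 to 8.93, -31.9 to -17.9 and -15.4 to -3.72 for neutrophil-like, 1.25 to 2.72, -0.45 to 1.09, -3.53 to -2.42 and -2.12 to -0.364 for classical-monocyte-like and -3.23 to -1.42, -6.13 to -0.595, 3.66 to 6.14 and 3.03 to 8.56 for T-cell-like cells. The neutrophil-like share with AREG-KO tumors reversed without pool 4 of the unirradiated (-2.78) or pool 3 of the irradiated AREG-KO library (-5.74). Outside the neutrophil-like class, the T-cell-like share reversed to 2.93 with irradiation of AREG-sufficient tumors and to -0.866 between irradiated genotypes, and was 5.75 (exact p = 0.0286) between unirradiated ones, and in the same setting the classical-monocyte-like share with irradiation of AREG-sufficient tumors was 9.36 (exact p = 0.0286). Leiden resolution 2 reversed the classical-monocyte-like share with AREG-KO tumors to -0.0182, and doublets kept gave -2.92 (exact p = 0.0286) between irradiated genotypes. The cause of these reversals was not tested. The rise of the neutrophil-like share was 13.1 points without Rag1-positive cells in the denominator and 15.8 without the 3 pools (both exact p = 0.0571). Without those cells in the denominator other shares moved over 1.5 times, with irradiation of AREG-KO tumors to 6.8 for neutrophil-like, 1.17 for classical-monocyte-like and -1.71 for T-cell-like cells. Between irradiated genotypes the T-cell-like share was 7.02. Without the 3 pools that of neutrophil-like cells was 14.8 with irradiation of AREG-KO tumors and -11.4 between irradiated genotypes. That of classical-monocyte-like cells was 1.25 and 1.2 with irradiation of AREG-sufficient and AREG-KO tumors, and -2.12 between unirradiated genotypes. Areg in neutrophil-like cells with irradiation of AREG-KO tumors ranged from -1.29 to 0.033 with 1 pool left out (0.0043 without pool 3 of the unirradiated, 0.033 without pool 2 of the irradiated AREG-KO library) and reversed to 0.28 without the 3 pools.

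The hashtag numbers do not pair pools across libraries: same-number pools correlated with a mean r of -0.0214 to 0.0106, and the replicate block moved no count over 1.5 times, while 20 of 164 named genes lost their call with it. Of 188 called named genes, 100 kept the call with every pool left out and 88 lost it at least once, 98 lost it without the 3 pools, 46 of 146 with free RNA subtracted, 38 of 133 with only the groups of the contrast, and none of 139 with DESeq2; no called gene reversed. Library sums were not thinned, as the hashtag condition held. Small changes are often missed: of simulated log2 changes of 0.5, 30.8 to 38.5% were found.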

Other observations

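Tests in this part were chosen after the results were seen, except the gene, list and share tests, which were fixed before the data were examined. NK-cell-like cells with unirradiated AREG-KO tumors had more MHC class II transcripts, H2-Aa (0.95 ± 0.21) and H2-Ab1 (0.92 ± 0.21), and less Ulk1, an autophagy kinase (-1.22 ± 0.24), Dpy19l4 (-1.20 ± 0.29) and Il31ra (-0.80 ± 0.10) than with AREG-sufficient tumors; 4 of 5 class II genes were called, 4 adjusted over the list alone (median 0.92, adjusted p = 4.6e-09, and 0.00735 with an estimated correlation). The class II genes are transcripts of B cells and antigen-presenting cells, and B-cell-like cells made up 12.8 ± 4% of cells with AREG-sufficient and 24.1 ± 10.2% with AREG-KO tumors; free RNA was not subtracted in NK-cell-like cells, and the cause was not tested. In NK-cell-like cells Rgs16, a brake on chemokine receptor signalling (-1.04 ± 0.28), Simc1 (-0.72 ± 0.20) and Ahdc1 (-0.71 ± 0.17) fell with irradiation of AREG-sufficient tumors, beside rises of the neutrophil transcripts Retnlg (2.31 ± 0.15), Wfdc17 (2.27 ± 0.17) and S100a8 (1.96 ± 0.08). The myeloid suppression list rose there in 13 of 17 (13 up and 2 down adjusted over the list alone; median 1.36, adjusted p = 2.8e-87, and 2.2e-07 with an estimated correlation).

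B-cell-like cells had lower MHC class II genes after irradiation of AREG-KO tumors, 5 of 10 called and 8 adjusted over the list alone (median -0.27, adjusted p = 4.2e-15, and 0.0379 with an estimated correlation). Lilr4b (1.01 ± 0.18), Emb (0.91 ± 0.19) and Clec4e, a receptor of myeloid cells (0.79 ± 0.17), rose. Bcl2a1b (-0.92 ± 0.19), AY036118 (-0.69 ± 0.07) and Hmgn2 (-0.67 ± 0.11) fell. Free RNA, not subtracted in B-cell-like cells, remains possible for Lilr4b and Clec4e. Between irradiated groups Ptpn22 was higher with AREG-KO tumors (1.52 ± 0.21), as were Emb (1.10 ± 0.23) and Sema5a (1.01 ± 0.23). The neutrophil transcripts Retnlg (-1.69 ± 0.11), Ifitm1 (-1.63 ± 0.11) and Slpi (-1.48 ± 0.21) were lower. Immediate early genes in B-cell-like cells were lower in 4 of 18 (11 adjusted over the list alone; median -0.29, adjusted p = 3.5e-13, and 0.0267 with an estimated correlation).

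Some genes were called the same way in all 5 large classes, counted with all pools: 44 with irradiation of AREG-sufficient tumors (43 higher, 1 lower), 4 with AREG-KO tumors (2 and 2), 11 between irradiated genotypes (4 and 7), 27 between unirradiated ones (24 and 3) and 47 for the interaction (45 and 2). Most of the 44, 27 and 47 are ribosomal protein or respiratory chain genes, joined by Tmsb10. Camk1d and Cdk8 rose and AY036118 fell in all 5 classes with irradiation of AREG-KO tumors. Calls of both irradiation contrasts shared 1 gene in neutrophil-like, 4 in classical-monocyte-like (AY036118, Gm2000, Oas1a and Plac8) and 7 in T-cell-like cells, where independence would give 0.197, 0.104 and 1.22, while the log2 changes of all genes correlated at -0.15, -0.0129 and -0.00274. A cluster with genes of red blood cells, a type outside the sort, among its leading genes held 1401 cells before doublet removal and was left unnamed. Its cells, 1.18 to 11.2% of kept cells per pool, stay in the denominator of every share of kept cells and in the Areg and Egfr levels over all cells. Alveolar-macrophage-like cells were 0.443 ± 0.181% of cells with irradiated AREG-sufficient and 1.68 ± 1.01% with irradiated AREG-KO tumors (n = 4, exact p = 0.0286, 1 of many classes compared). Pool profiles varied by library (24.4 to 28.1% of variance over the 5 classes) more than by hashtag number (17 to 19%).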
